A study of Caenorhabditis elegans with 22 samples.

How the data were processed

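Gene expression was measured on 22 Affymetrix arrays of Caenorhabditis elegans, with 4 arrays of untreated wild type and 3 arrays of each of 6 other groups. The other groups were the mutants isp-1(qm150), nuo-6(qm200) and ced-4(n1162), the isp-1 ced-4 and nuo-6 ced-4 double mutants, and wild type treated with 0.1 mM paraquat. Per the labels, hermaphrodites from an egg lay of 4 hours were picked by hand as young adults and washed, total RNA was taken, and biotin-labelled cRNA was made with a kit that copies from the 3' end of the transcripts. The labels call the samples biological replicates and do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may in part be technical.

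The values used are the deposited log2 expression values of the authors' table, made with GCRMA per the submitters' processing notes. As a method, GCRMA corrects the background by probe sequence, normalizes arrays by quantiles and summarises the probes of a probe set. Its version and settings, and whether all 22 arrays were normalized together, are not given in the sources used here, and arrays normalized apart would differ between groups for that reason too. The log base was not stated and was read from the range of the table, from 0.926 to 15.25, which is that of log2 intensities. Low values lie close to the background correction, so differences between groups that are both low are uncertain. Where a single group is low, the size of a difference is uncertain. Quantile normalization assumes that most transcripts do not shift together. An array has no read depth, and the number of arrays limits the precision.

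The table held 22625 probe sets, of which 77 were control probe sets and were left out. A probe set was tested when it reached the median of the whole table, 3.68, on at least 3 arrays, which kept 12639 of the other 22548. Genes were named from the platform annotation, with symbols updated by entrez ID, which was found for 20701 of the 20766 probe sets with 1 symbol. Of the tested probe sets 11963 had 1 symbol, 464 had several and 212 had none, and no gene was named from the last 2 kinds. A gene was represented by its probe set with the highest mean over all arrays, which gave 9647 tested genes of 17118 on the array. Probe sets of the kinds that may bind more than 1 transcript are uncertain, and many collagens, C-type lectins and sperm genes are read by them. This holds among others for isp-1, wrt-4, sqt-1, col-113, col-120, mlt-11, dpy-5, abu-15, pgp-5, cav-1, cht-1, clec-17, clec-174, clec-190, clec-266, mpst-4, spe-18, myo-1, mup-2, aakg-2, aldo-1, atfs-1, cysl-2, trx-2 and maph-1.2. No coordinates are given, since no genome build is given in the sources used here.

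All 7 groups were fitted in 1 means model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), so that every comparison shared 1 estimate of the spread per probe set. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Adjusted p-values of genes below are limma's, differences are on the log2 scale, SE is the standard error from the model, and values of groups are means ± SD. The comparisons were each mutant and paraquat against wild type, nuo-6 against isp-1, each double mutant against its single mutant and against ced-4, and the interaction of each mitochondrial mutation with ced-4. A probe set was in the common set when it was called in the same direction in isp-1, nuo-6 and paraquat. Its score on an array was the mean difference from wild type over the set, with the sign turned for the lower part.

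For gene lists, camera was run with a preset correlation of 0.01 and again with an estimated correlation, and fry beside it, over 39 lists in 11 comparisons with Benjamini-Hochberg adjustment over the lists. The adjusted p of a list, without further words, is camera's with the preset correlation. Counts of members are given over all probe sets tested, and again adjusted over the list alone. The model, the filter, the lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took the 3 mutated genes, then per comparison the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays in the 2 groups did not overlap, 2 more each way with only a sequence name, up to 4 members with the smallest p of each list described, and the 5 largest interactions each way.

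Alternatives were another filter, no filter, cyclic loess between arrays, median centring, the replicate number as a block, a fit of only the groups compared, eBayes with trend and robust options, and leaving out each array in turn. The steps were tested on simulated data with 200 of 12639 probe sets changed. With the arrays of isp-1 against wild type, 96% of changes of 2 on the log2 scale were recovered, 72.5% of changes of 1 and 0% of changes of 0.5. For isp-1 ced-4 against ced-4 the shares were 93.5%, 66% and 0%. The simulated groups all had the same spread. In most comparisons of the data far larger shares were called, such as 32.8% in nuo-6, which makes the Benjamini-Hochberg cut less strict. The recovered shares therefore hold for the simulated setting only, and changes under 0.5 were called in the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.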

Results

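The arrays compared young adult worms that carry mutations in the mitochondrial respiratory chain with wild type worms exposed to paraquat, a redox-cycling compound that makes superoxide. isp-1 encodes the iron-sulfur protein of complex III and nuo-6 a subunit of complex I. ced-4 encodes the adaptor that activates the caspase CED-3 in the intrinsic apoptosis pathway. The labels ask for an expression pattern common to the mitochondrial mutants and to paraquat, and the double mutants set the same mitochondrial mutations in a ced-4 background. The median SD between arrays of a group was 0.298 in wild type, 0.242 in isp-1, 0.214 in nuo-6, 0.196 in paraquat and 0.192 in isp-1 ced-4, but 0.124 in ced-4 and 0.126 in nuo-6 ced-4. Wild type replicate 1 stood apart on the second principal component, at 5.21 against 49.05, 61.61 and 54.24 for the other wild type arrays.

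The mutated genes were read first. The ced-4 transcript (C35D10.9, chromosome III) was 7.62 ± 0.26 in wild type (n = 4), 5.72 ± 0.15 in ced-4, 5.70 ± 0.16 in isp-1 ced-4 and 5.09 ± 0.16 in nuo-6 ced-4 (n = 3 each). It fell by 1.89 in ced-4 (adjusted p = 8.23e-08), by 1.87 in isp-1 ced-4 against isp-1 (adjusted p = 9.79e-06) and by 2.50 in nuo-6 ced-4 against nuo-6 (adjusted p = 8.32e-09). In nuo-6 ced-4 it was also lower than in ced-4, by -0.63 (adjusted p = 0.0187), a call that ended without ced-4 replicate 2, where the difference was -0.55. With paraquat the ced-4 transcript rose by 0.76 (SE 0.16, adjusted p = 0.00117). The isp-1 transcript differed by 0.04 between isp-1 and wild type (adjusted p = 0.769) and the nuo-6 transcript by 0.28 between nuo-6 and wild type (adjusted p = 0.049), the latter not past the threshold without nuo-6 replicate 2 (0.24) or after loess (0.25). Neither transcript was lower in its own mutant, so these transcripts do not check which arrays carry the mutations.

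**Figure D1:**
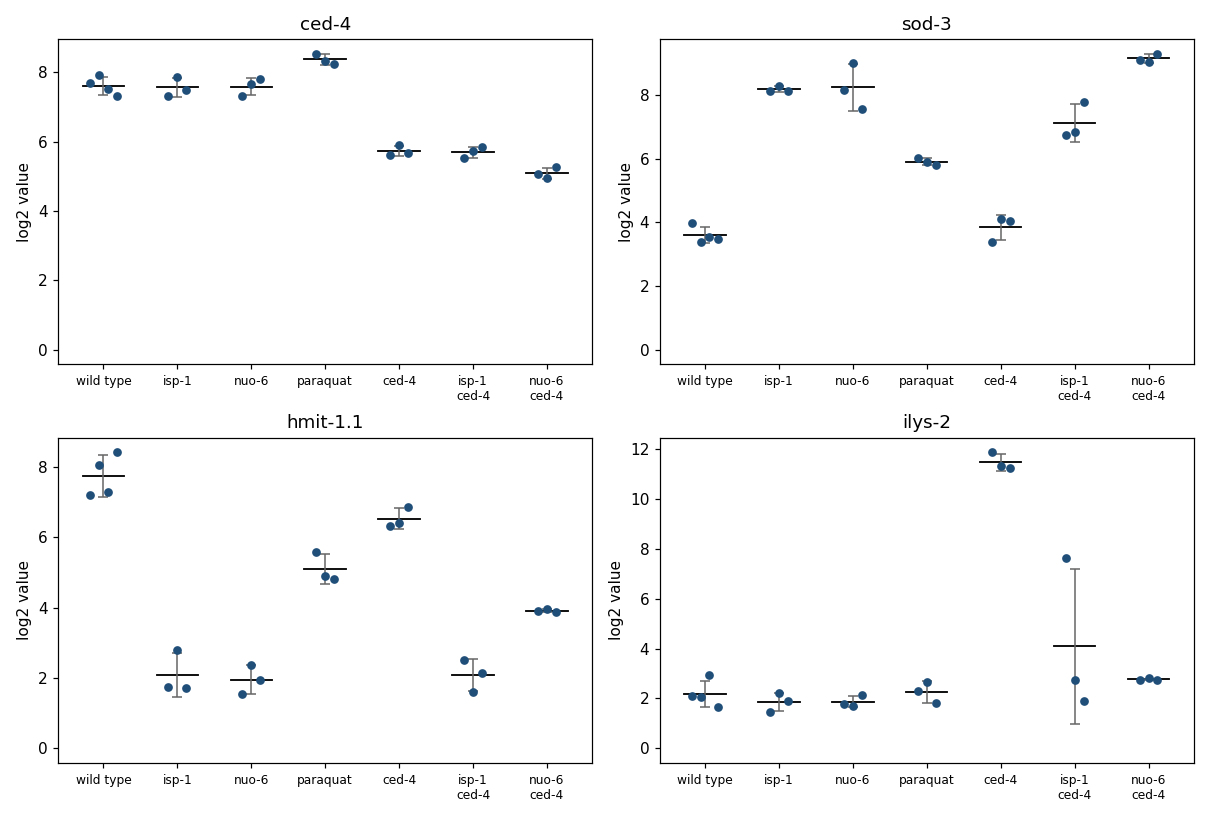
Log2 expression of ced-4, sod-3, hmit-1.1 and ilys-2 on each array, by group, with the group mean (line) and SD (bar). ced-4 lies lower in the 3 groups that carry its mutation, sod-3 is higher in isp-1, nuo-6 and paraquat than in wild type, hmit-1.1 is lower in those groups, and ilys-2 is high in ced-4, at 11.48 against 2.19 in wild type, and on 1 of the isp-1 ced-4 arrays.

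In isp-1, sod-3, the inducible mitochondrial superoxide dismutase, stood at 8.19 ± 0.10 (n = 3) against 3.60 ± 0.26 (n = 4) in wild type, a rise of 4.59 (SE 0.29, adjusted p = 1.02e-08). hmit-1.1, a proton-coupled myo-inositol transporter, fell by 5.67 (SE 0.33, adjusted p = 3.89e-09), and pgp-5, an ABC transporter, fell by 4.36 (SE 0.30, adjusted p = 3e-08). The genes C38D9.2 and F15D4.5, known only by sequence names, rose by 8.29 and 6.95. Among the other largest rises were scrm-4, of the phospholipid scramblases, at 4.39, sysm-1 at 4.01 and rips-1 at 3.84. Next came the cytochrome P450 genes cyp-14A1 and cyp-33C8 at 3.68 and 3.62, the glutathione S-transferase gst-14 at 3.54 and cnc-3, an antimicrobial caenacin, at 3.36. The largest falls included the collagen gene col-149, by 4.06, the infection response genes irg-1 and irg-4, by 3.92 and 3.13, and the glucuronosyltransferase gene ugt-26, by 3.80. Also lower were clec-47, of the C-type lectins, by 3.47, and gpdh-1, a glycerol-3-phosphate dehydrogenase induced by osmotic stress, by 3.12.

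Of 14 HIF-1 associated genes 9 rose in isp-1, 10 adjusted over the list alone (adjusted p = 0.000142, adjusted p = 0.0732 with an estimated correlation). They included nhr-57 at 2.49, sqrd-1, the sulfide quinone oxidoreductase, at 2.48, and cysl-2 at 2.14. Of 62 neuropeptide genes 28 rose, 32 adjusted over the list alone, among them nlp-16 at 1.62 and flp-2 at 1.35 (adjusted p = 6.59e-06, adjusted p = 0.416 with an estimated correlation). Of 21 genes of superoxide and peroxide detoxification 7 rose, 8 adjusted over the list alone, with the mitochondrial thioredoxin reductase trxr-2 at 1.53 and the peroxiredoxin prdx-3 at 0.49 (adjusted p = 0.0149, adjusted p = 0.132 with an estimated correlation). Of 27 glutathione S-transferases 9 rose, 15 adjusted over the list alone (adjusted p = 0.00165, adjusted p = 0.409 with an estimated correlation). Among 17 mitochondrial chaperones and proteases 6 rose and 1 fell, 11 and 1 adjusted over the list alone. timm-17B.2, of the inner membrane import machinery, rose by 1.58 and atfs-1, the regulator of the mitochondrial unfolded protein response, by 1.18 (adjusted p = 0.0105, adjusted p = 0.416 with an estimated correlation). Among markers, 5 of 56 sperm genes fell and 1 rose, 4 and 1 adjusted over the list alone (adjusted p = 0.000707, adjusted p = 0.741 with an estimated correlation), and 6 of 31 oocyte and early embryo genes rose, 6 adjusted over the list alone (adjusted p = 0.00821, adjusted p = 0.718 with an estimated correlation). Of 27 intestine markers 6 fell and 1 rose, 7 and 1 adjusted over the list alone (adjusted p = 0.0217, adjusted p = 0.431 with an estimated correlation and 0.0887 after loess). In all, limma called 2775 probe sets in isp-1, 1558 higher and 1217 lower, and 1173 changed at least 2-fold. After loess the split was 1220 higher and 1610 lower, so the balance of directions is not settled, and a fit of only isp-1 and wild type called 716.

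The nuo-6 mutation moved many of the same genes as isp-1, with 1250 probe sets higher and 1047 lower in both. These counts include isp-1 replicate 1, which correlated with nuo-6 replicate 1 at 0.993, more closely than with the other isp-1 arrays. sod-3 rose by 4.65 (SE 0.29, adjusted p = 6.17e-09), scrm-4 by 5.23, C38D9.2 by 7.99 and F15D4.5 by 7.90, while hmit-1.1 fell by 5.80 (SE 0.33, adjusted p = 2.66e-09), F42A10.7 by 4.76 and pgp-5 by 4.08. Further large rises were those of nta-1 at 5.07, osg-1 at 4.63, the beta-tubulin tbb-6 at 4.53, hrg-9, of the heme-responsive genes, at 4.47, saeg-2 at 4.21 and clc-24, of the claudin-like family, at 4.11. Further falls were those of cth-1, a cystathionine gamma-lyase, by 4.19, asm-3, an acid sphingomyelinase, by 4.01, irg-4 by 3.89, irg-1 by 3.86 and col-149 by 3.66. The ribosomal RNA probe set rrn-3.1 fell by 4.18 (SE 1.15) with an SD of 3.57 between the nuo-6 arrays, and without nuo-6 replicate 3 it was lower by -2.13 and not past the threshold.

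In nuo-6, 10 of the 14 HIF-1 associated genes rose, 10 also adjusted over the list alone, led by the flavin monooxygenase fmo-2 at 4.01, sqrd-1 at 3.23 and nhr-57 at 2.71 (adjusted p = 9.88e-05, adjusted p = 0.0415 with an estimated correlation). Of the 21 superoxide and peroxide genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone, with trxr-2 at 2.03, trx-2 at 0.67 and prdx-3 at 0.69 (adjusted p = 0.00202, adjusted p = 0.0415 with an estimated correlation). Of 27 complex I genes 18 rose and 1 fell, 20 and 1 adjusted over the list alone, with nduf-9 at 0.37 and nduv-2 at 0.38, while nduf-2.2 fell by 0.63 (adjusted p = 0.000383, adjusted p = 0.19 with an estimated correlation). Of 16 glycolytic genes 10 rose and 1 fell, 12 and 1 adjusted over the list alone, led by the aldolase aldo-1 at 2.32 and the lactate dehydrogenase ldh-1 at 1.93 (adjusted p = 7.09e-05, adjusted p = 0.19 with an estimated correlation). The mitochondrial proteases ymel-1 and spg-7 rose by 1.77 and 1.95 among 10 of 17 mitochondrial chaperones and proteases, 12 higher and 1 lower adjusted over the list alone (adjusted p = 0.000878, adjusted p = 0.19 with an estimated correlation). Of 38 cytochrome P450 genes 18 rose and 3 fell, 19 and 3 adjusted over the list alone, with cyp-14A1 at 4.04 (adjusted p = 0.000137, adjusted p = 0.19 with an estimated correlation). Of the 56 sperm genes 5 fell and 1 rose, 4 and 1 adjusted over the list alone (adjusted p = 0.00113, adjusted p = 0.691 with an estimated correlation), and 8 of 31 oocyte and early embryo genes rose, 7 adjusted over the list alone (adjusted p = 0.0343, adjusted p = 0.691 with an estimated correlation). limma called 4150 probe sets, 2275 higher and 1875 lower, with 1669 changed at least 2-fold. After loess the split was 1928 higher and 2261 lower, so the more frequent direction is not settled, and a fit of only nuo-6 and wild type called 2190.

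Set against each other, the mutants differed in 1 called probe set, that of maph-1.2, which was lower in nuo-6 than in isp-1 by -1.31 (SE 0.19, adjusted p = 0.0263), and 1390 passed an unadjusted p under 0.05. The maph-1.2 call ended without isp-1 replicate 3, where the difference was -1.198. Without isp-1 replicate 1, 753 probe sets were called, without isp-1 replicate 2 or 3 or nuo-6 replicate 2, or in a fit of only these groups, limma called 0, and without nuo-6 replicate 3 it called 3. isp-1 replicate 1 correlated with nuo-6 replicate 1 at 0.993 across all probe sets and with isp-1 replicates 2 and 3 at 0.976 and 0.967, so the closeness of the 2 mutants rests in part on it.

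Genes expressed in sperm were lower with paraquat and genes of oocytes and early embryos higher. Of 56 sperm genes 55 fell and 1 rose, the same adjusted over the list alone, among them spe-4, the presenilin of sperm, by 3.61, the kinase gene spe-6 by 2.95 and spe-12 by 2.03 (adjusted p = 1.18e-17, adjusted p = 0.544 with an estimated correlation). Of 31 oocyte and early embryo genes 29 rose, 30 adjusted over the list alone, with puf-5 at 1.26, spn-4 at 1.12, egg-2 at 1.05 and the katanin subunit gene mei-1 at 1.03 (adjusted p = 5.03e-10, adjusted p = 0.544 with an estimated correlation). sod-3 rose by 2.31 (SE 0.29, adjusted p = 6.55e-06), a smaller rise than in the mutants, and hmit-1.1 fell by 2.65 (SE 0.33, adjusted p = 6.27e-06).

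Among the largest rises with paraquat were those of the aspartyl protease asp-17 at 4.08, the caveolin cav-1 at 3.96, pzf-1 at 3.72, and the innexin inx-2 at 3.47. Also higher were skr-15 at 3.33, the T-box gene sea-1 at 3.29, vet-2 at 2.98 and the chitinase cht-1 at 2.96. Among the largest falls were those of F26A3.5 by 5.60, clc-10 by 4.49, catp-4 by 4.46 and gskl-2 by 4.28. Further, mpst-4 fell by 4.18, clec-79 by 4.12, his-70, a histone H3 gene, by 4.10 and pei-1 by 4.09. rrn-3.1 fell by 5.61 with an SD of 2.33. Of 28 genes of DNA replication and mitosis 19 rose, 19 adjusted over the list alone, among them rnr-2 of the ribonucleotide reductase at 0.95 and pcn-1, the replication clamp, at 0.68 (adjusted p = 0.00017, adjusted p = 0.544 with an estimated correlation). Of 46 UDP-glucuronosyltransferases 18 fell, 18 adjusted over the list alone, with ugt-41 by 2.67 and ugt-62 by 1.37 (adjusted p = 8.13e-05, adjusted p = 0.544 with an estimated correlation). Of 27 complex I genes 11 fell, 13 adjusted over the list alone, with nuo-6 by 0.45 and ndub-3 by 0.55 (adjusted p = 0.003, adjusted p = 0.544 with an estimated correlation). On the same arrays 8 of 27 intestine markers fell, 7 adjusted over the list alone, with a list mean of -0.28 and an SD of 0.081 in wild type (adjusted p = 0.0484, adjusted p = 0.544 with an estimated correlation and 0.172 after loess). Of 25 germline genes 9 rose and 1 fell, the same adjusted over the list alone, with a list mean of 0.311 and an SD of 0.098 in wild type (adjusted p = 0.0484, adjusted p = 0.544 with an estimated correlation and 0.116 after loess). limma called 5251 probe sets, 3340 higher and 1911 lower, and 2076 changed at least 2-fold. The median of all tested probe sets lay at 0.125 above wild type, and after loess it lay at -0.021 and the split was 2247 higher and 2570 lower. With the means of the sperm and molting lists as covariates, an alternative chosen after seeing the data, limma called 1188, and the median SE was 0.326 in place of 0.198.

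The comparison the labels ask for found 1307 probe sets that changed in the same direction in isp-1, nuo-6 and paraquat. Of these 569 were higher and 738 lower, in 443 and 623 genes. After loess the split was 345 and 944, and with the sperm and molting covariates the set held 406 probe sets, of which 389 were shared with the 1307. Ranked by the smallest of the 3 changes, the rises with a gene name began with sod-3, dmd-9, of the DM domain family (2.40, 2.63 and 1.90 in isp-1, nuo-6 and paraquat), tyms-1, the thymidylate synthase (2.08, 2.74 and 1.84), dmd-6 (2.02, 1.70 and 2.00), ztf-25, phat-3, fbxa-153 and nhr-57. The falls began with irg-4, hmit-1.1, msrp-1 (-2.53, -3.64 and -3.61), the transporter gene sulp-6, clc-10, spe-27, a gene of sperm activation (-2.09, -2.34 and -3.15), ugt-53 and mpst-4. For clc-10 the isp-1 call ended without isp-1 replicate 2, where the difference was -2.11 in place of -2.18. Changes of at least 2-fold in all 3 were counted for 68 higher and 498 lower probe sets. By Fisher's exact test over the lists, 5 of 14 HIF-1 associated genes (adjusted p = 0.011) and 6 of 31 oocyte and early embryo genes (adjusted p = 0.0489) were among the higher part, and 4 of 56 sperm genes were among the lower part (adjusted p = 1).

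The 3 comparisons share the wild type arrays. Changes in isp-1 and nuo-6 correlated at 0.886 across probe sets against 0.42 simulated with unchanged groups, with a covariance of 0.479 against 0.029 simulated. For isp-1 and paraquat the correlation was 0.625 against 0.448 and the covariance 0.426 against 0.031, and for nuo-6 and paraquat 0.551 against 0.444 and 0.447 against 0.031. Genes are not independent replicates here. The simulation drew probe sets independently with the same spread for every group, while the shared wild type arrays had the largest median SD, 0.298. The simulated values may thus be too low. Independent lists of the same sizes would share 74.1 higher and 27.3 lower probe sets among all 3. With isp-1 and nuo-6 set against different pairs of wild type arrays, an alternative chosen after seeing the data, their changes correlated at 0.654 to 0.776, with isp-1 replicate 1 included throughout. With isp-1 and paraquat set against different pairs of wild type arrays, 297 to 822 probe sets were lower in both, from 2.41 to 4.65 times the number for independent lists, and 306 to 676 were higher in both, from 1.07 times. With nuo-6 and paraquat so split, the lower part was from 2.09 times and the higher part from 0.983 times that number.

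**Figure D2:**
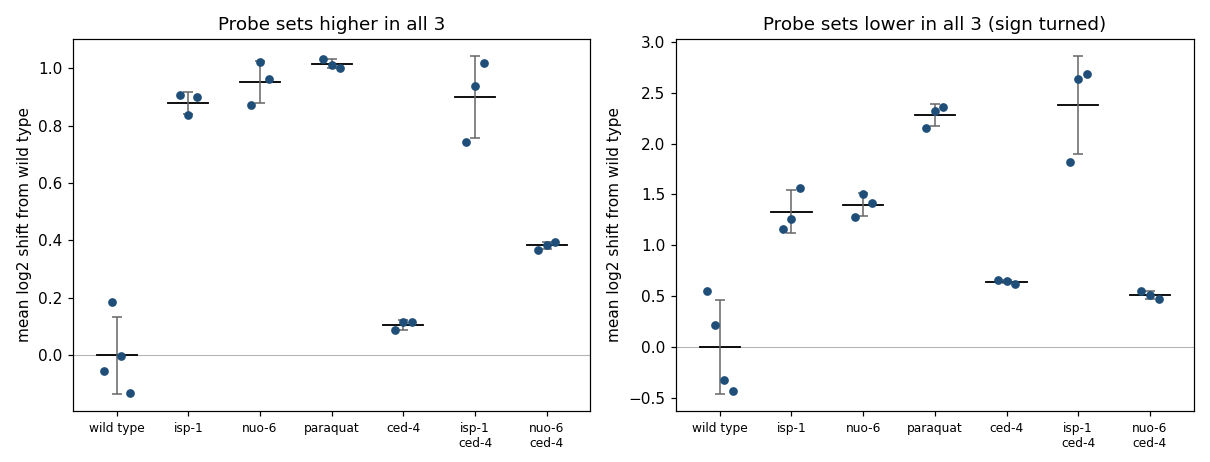
Mean log2 shift from wild type on each array over the higher (left) and the lower (right, sign turned) parts of the common set, by group, with the group mean (line) and SD (bar). On the left isp-1 ced-4 lies at 0.90 and nuo-6 ced-4 at 0.38 against 0.11 for ced-4, and on the right isp-1 ced-4 lies at 2.38, nuo-6 ced-4 at 0.51 and ced-4 at 0.64.

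In the ced-4 background the common set was followed by its score. The score was 1.13 ± 0.12 in isp-1, 1.204 ± 0.097 in nuo-6, 0.409 ± 0.008 in ced-4, 1.74 ± 0.33 in isp-1 ced-4 and 0.453 ± 0.015 in nuo-6 ced-4 (n = 3 each). isp-1 ced-4 lay above ced-4 by 1.33 and above isp-1 by 0.60, and nuo-6 ced-4 lay above ced-4 by 0.04 and differed from nuo-6 by -0.75. The isp-1 and nuo-6 arrays helped to choose the set, so only the comparisons with ced-4 are independent of it. With the set chosen without the single mutant in question, isp-1 ced-4 lay above isp-1 by 0.611 and nuo-6 ced-4 differed from nuo-6 by -0.702. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 arrays allow, so none can pass 0.05. isp-1 ced-4 differed from isp-1 by 0.02 in the higher part (exact permutation p = 0.8) and by 1.05 in the lower part (exact permutation p = 0.1). The score of the lower part was 1.824 on isp-1 ced-4 replicate 1 and 2.636 and 2.684 on replicates 2 and 3. Those replicates also had lower sperm list means than replicate 1, so a share of sperm RNA in this difference stays open. In nuo-6 ced-4 the parts went apart: the higher part lay above that of ced-4 by 0.28 and the lower part differed from it by -0.14, and with the median in place of the mean the score differed by -0.017 (exact permutation p = 0.3). When the set was chosen without nuo-6 the difference was 0.006 (exact permutation p = 0.7).

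In ced-4 worms genes of the cuticle and of molting rose. Of 19 molting cycle genes 17 rose, 17 adjusted over the list alone, with wrt-4, of the hedgehog-related family, at 6.99, mlt-8 at 5.13, wrt-6 at 4.03 and ptr-4 at 2.94 (adjusted p = 6.7e-25, adjusted p = 0.00128 with an estimated correlation). Of 117 cuticle collagens 61 rose and 11 fell, 69 and 15 adjusted over the list alone, with col-91 at 5.24, col-156 at 5.22 and col-113 at 4.61 (adjusted p = 8.42e-23, adjusted p = 0.19 with an estimated correlation). The invertebrate-type lysozyme ilys-2 stood at 11.48 ± 0.34 (n = 3) against 2.19 ± 0.53 (n = 4), a rise of 9.30 (SE 0.83, adjusted p = 1.22e-07). The molting list mean lay at 2.60 ± 0.14 above wild type in ced-4. Of 17 hypodermis genes other than collagens 6 rose, 7 adjusted over the list alone, with grl-7 at 5.45 (adjusted p = 0.00116, adjusted p = 0.187 with an estimated correlation), and the list mean was 0.95 in ced-4 and 0.795 in nuo-6 ced-4, with an SD of 0.174 in wild type. Of 28 muscle genes 5 fell, 6 adjusted over the list alone (adjusted p = 0.0274, adjusted p = 0.618 with an estimated correlation and 0.128 after loess), and the list mean was -0.39 with an SD of 0.343 in wild type.

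**Figure D3:**
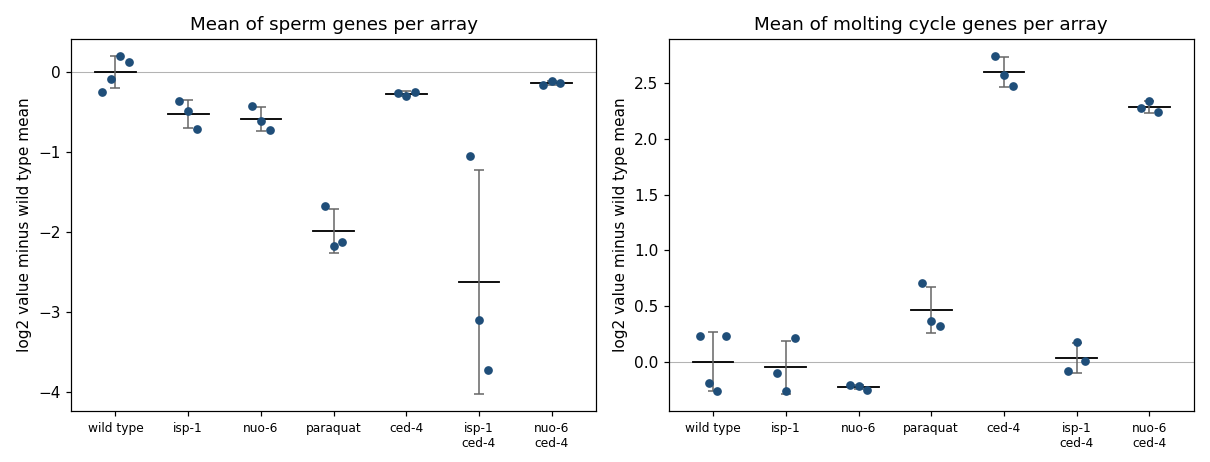
Mean log2 difference from wild type over the sperm list (left) and the molting cycle list (right) on each array, by group, with the group mean (line) and SD (bar). The molting list lies at 2.60 in ced-4 and 2.29 in nuo-6 ced-4 but at 0.03 in isp-1 ced-4, and the sperm list lies lowest in paraquat and on isp-1 ced-4 replicates 2 and 3.

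Other large rises in ced-4 were those of R12E2.7 at 8.28, F49E12.10 at 7.23, the collagen genes col-48, sqt-1, col-49 and col-97 at 7.08, 6.97, 6.97 and 6.63, cyp-13A6 at 6.79 and clec-52 at 6.50. Of 40 lysozymes, saposins and antimicrobial peptides 11 rose and 2 fell, 13 and 2 adjusted over the list alone, with lys-10 at 6.49 and the saposin-like spp-13 at 3.45 (adjusted p = 0.000167, adjusted p = 0.19 with an estimated correlation). The falls were led by acs-2, an acyl-CoA synthetase, by 3.91 (SE 0.58, adjusted p = 8.5e-05), aakg-2, a gamma subunit of AMP-activated kinase, by 3.75 and idpp-15 by 3.43. The alcohol dehydrogenase adh-1 fell by 3.20, idpp-14 by 2.96, pgp-5 by 2.90, vap-2 by 2.81 and irg-1 by 2.79. cpt-5, a carnitine palmitoyl transferase gene, fell by 2.16 and kat-1, the last enzyme of beta-oxidation, by 0.68. Of 19 genes of the TCA cycle 7 fell, 9 adjusted over the list alone, with mdh-2 by 0.68 and cts-1, the citrate synthase, by 0.53 (adjusted p = 0.00116, adjusted p = 0.19 with an estimated correlation). limma called 1999 probe sets, 823 higher and 1176 lower, with 1014 changed at least 2-fold. Without wild type replicate 1 the count was 3404, and without ced-4 replicates 1, 2 and 3 it was 1275, 1163 and 1221. A fit of only ced-4 and wild type called 853, 563 higher and 290 lower, so the more frequent direction is not settled, and with the sperm and molting covariates 4 were called, at a median SE of 0.933 in place of 0.198.

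Sperm genes, neuropeptides and muscle genes were lower in isp-1 ced-4 than in isp-1. Of the 56 sperm genes 54 fell, 55 adjusted over the list alone, with ssp-19 by 3.16 and spe-4 by 2.40 (adjusted p = 1.23e-20, adjusted p = 0.446 with an estimated correlation). The sperm list mean was -1.05 on isp-1 ced-4 replicate 1 and -3.097 and -3.730 on replicates 2 and 3, so these arrays differ widely among themselves. Of 62 neuropeptide genes 35 fell and 3 rose, 41 and 3 adjusted over the list alone, with nlp-16 by 2.51 and nlp-1 by 1.68 (adjusted p = 1.25e-08, adjusted p = 0.446 with an estimated correlation). Of 28 genes of body wall and pharyngeal muscle 19 fell and 1 rose, 21 and 2 adjusted over the list alone, with the myosin myo-1 by 3.40, the troponin genes tnc-2 and tni-4 by 2.82 and 2.32 and mup-2 by 0.89 (adjusted p = 3.76e-06, adjusted p = 0.446 with an estimated correlation).

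The troponin T gene tnt-4 fell by 4.29, spe-18 by 3.99, msrp-6 by 3.84, sss-2 by 3.77, ssp-35 by 3.76, ttbk-8.2 by 3.75, gskl-2 by 3.70 and nsph-2 by 3.58. Among the largest rises were those of the linker histone his-24 at 4.49, clec-190 at 4.33 (SE 0.20, adjusted p = 3.66e-10), cht-1 at 4.33, clec-266 at 4.19, clec-174 at 3.71, cav-1 at 3.24, skr-8 at 3.09 and clc-11 at 3.03. Of 12 genes that act in engulfment of cell corpses 8 rose and 1 fell, 9 and 1 adjusted over the list alone, with ced-10, a Rac GTPase, at 1.08 and ced-6 at 0.94 (adjusted p = 0.00677, adjusted p = 0.446 with an estimated correlation). Of the 14 HIF-1 associated genes 8 fell, 8 lower and 1 higher adjusted over the list alone, with nhr-57 by 1.44 and cah-4 by 1.08 (adjusted p = 0.0309, adjusted p = 0.446 with an estimated correlation). Of the 31 oocyte and early embryo genes 15 rose, 15 adjusted over the list alone, with mex-1 at 1.54 and chs-1 at 0.90 (adjusted p = 1.8e-05, adjusted p = 0.494 with an estimated correlation). limma called 4193 probe sets, 2019 higher and 2174 lower, with 1812 changed at least 2-fold. Without isp-1 ced-4 replicate 2 the count was 2748, in a fit of only these groups 2088, and with the sperm and molting covariates 158.

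Cuticle and molting genes were higher in nuo-6 ced-4 than in nuo-6, as they were in ced-4 against wild type. The molting list mean was 0.03 in isp-1 ced-4, which carries the same ced-4 mutation. Earlier sampling of ced-4 and nuo-6 ced-4 is not settled, so the rise cannot be assigned to the mutation alone. Of the 19 molting cycle genes 18 rose, 18 adjusted over the list alone, with mlt-8 at 4.93, mlt-11 at 4.72, wrt-10 at 2.78 and ptr-4 at 2.01 (adjusted p = 1.62e-20, adjusted p = 0.00379 with an estimated correlation). Of the 117 collagens 68 rose and 8 fell, 75 and 9 adjusted over the list alone, with col-91 at 5.71 and col-156 at 5.26 (adjusted p = 2.89e-24, adjusted p = 0.207 with an estimated correlation). Of the 17 hypodermis genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 0.00334, adjusted p = 0.207 with an estimated correlation), and of the 28 muscle genes 7 fell, 7 adjusted over the list alone (adjusted p = 0.0425, adjusted p = 0.83 with an estimated correlation and 0.0701 after loess). All 5 vitellogenins, the yolk proteins, fell, also adjusted over the list alone, with vit-1 by 1.48 and vit-6 by 0.61 (adjusted p = 0.00129, adjusted p = 0.365 with an estimated correlation). Of the 31 oocyte and early embryo genes 20 fell, 22 adjusted over the list alone, with oma-1 by 1.51 and spn-4 by 1.09 (adjusted p = 1.32e-05, adjusted p = 0.591 with an estimated correlation).

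The largest single rises were those of Y47D7A.13 at 7.17, R12E2.7 at 6.99, col-48 at 6.69, dbd-2 at 6.68, and abu-15 at 6.51. Next came col-60 and col-97 at 6.46 each, sqt-1 at 6.44, col-120 at 6.32 and dbd-20 at 6.30. The falls included those of fat-7, a stearoyl-CoA desaturase, by 4.54 (SE 0.55, adjusted p = 8.49e-06), srlf-3 by 3.65, srlf-35 by 3.60, catp-3 by 3.30, the nuclear receptor nhr-114 by 3.26, clec-5 by 3.24, anmt-2 by 3.08 and idpp-16 by 2.96. Of the 19 TCA cycle genes 9 fell, 11 adjusted over the list alone, with dld-1 by 1.07 (adjusted p = 0.00129, adjusted p = 0.281 with an estimated correlation). limma called 3778 probe sets, 1420 higher and 2358 lower, and 1670 changed at least 2-fold. The median of all tested probe sets was -0.093, and 0.02 after loess. The split was 1867 higher and 1651 lower after loess and 1728 and 1746 after median centring, so which direction is the more frequent is not settled. The sperm and molting covariates left 0 by limma (966 at an unadjusted p under 0.05), at a median SE of 0.92 in place of 0.212.

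With ced-4 as the reference, isp-1 ced-4 lacked the high cuticle and molting signal. Of the 19 molting cycle genes 17 fell and 1 rose, the same adjusted over the list alone, with wrt-4 by 7.25, mlt-8 by 5.52, wrt-6 by 4.12 and ptr-4 by 3.08 (adjusted p = 1.97e-11, adjusted p = 0.0591 with an estimated correlation). Of the 117 collagens 77 fell and 14 rose, 81 and 15 adjusted over the list alone, with col-48 by 7.92, col-97 by 7.58 and sqt-1 by 7.50 (adjusted p = 1.12e-15, adjusted p = 0.369 with an estimated correlation). Of the 17 hypodermis genes 9 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.000628, adjusted p = 0.147 with an estimated correlation). Sperm genes were lower, with 53 of 56 called and 55 adjusted over the list alone, among them sss-2 by 4.54 and spe-12 by 1.80 (adjusted p = 7.61e-17, adjusted p = 0.516 with an estimated correlation), and the sperm list mean of isp-1 ced-4 without replicate 1 was -3.41 in place of -2.63. Of 31 oocyte and early embryo genes 29 rose, 30 adjusted over the list alone, with mex-1 at 1.28 and mei-1 at 0.88 (adjusted p = 6.42e-07, adjusted p = 0.516 with an estimated correlation).

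sod-3 rose in isp-1 ced-4 against ced-4 by 3.28 (SE 0.31, adjusted p = 1.92e-07) and the thioredoxin reductases trxr-1 and trxr-2 by 2.34 and 1.65. Of the 21 superoxide and peroxide genes 8 rose and 4 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.0828). The other largest rises were those of ZK177.9 at 6.93, C07G1.7 at 6.19, acs-2 at 5.29, clec-223 at 4.90, sysm-1 at 4.86, adh-1 at 4.68, and cyp-33C8 at 4.54. The C-type lectins clec-17 at 4.34, clec-222 at 4.31 and clec-266 at 4.29 also rose. Further falls were those of R12E2.7 by 8.86, Y47D7A.13 by 8.47, dpy-5, a gene of body shape, by 7.83, abu-15 by 7.69, ilys-2 by 7.39 and abu-8 by 7.28. Of the 93 nuclear hormone receptors 38 rose and 1 fell, 36 and 1 adjusted over the list alone, with nhr-90 at 1.72 (adjusted p = 0.00185, adjusted p = 0.402 with an estimated correlation). limma called 6594 probe sets, 3948 higher and 2646 lower, with 3114 changed at least 2-fold. The median of all tested probe sets was 0.171, and after loess it was 0.008 and the split 2701 higher and 3191 lower. Under the sperm and molting covariates limma called 0 (973 at an unadjusted p under 0.05), at a median SE of 1.01 in place of 0.212.

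In nuo-6 ced-4 against ced-4, glutathione S-transferases and SKN-1 and HIF-1 associated genes rose. Some marker lists moved too, in both directions. From ced-4 to nuo-6 ced-4 the list mean against wild type went from -0.296 to -0.689 for vitellogenins. For oocyte and early embryo genes it went from -0.019 to -0.259, for intestine from 0.025 to -0.19, and for sperm genes from -0.269 to -0.136. Of 27 glutathione S-transferases 15 rose, 16 adjusted over the list alone, with gst-15 at 3.28, gst-13 at 1.62 and gst-7 at 1.54 (adjusted p = 1.32e-09, adjusted p = 0.0137 with an estimated correlation). Of 23 SKN-1 associated genes 9 rose and 1 fell, 11 and 1 adjusted over the list alone, with alh-5 at 2.82, sdz-8 at 1.91 and gst-5 at 1.60 (adjusted p = 3.98e-06, adjusted p = 0.00602 with an estimated correlation). Of 14 HIF-1 associated genes 8 rose, 10 adjusted over the list alone, with cysl-2 at 2.39, sqrd-1 at 2.33 and nhr-57 at 2.06 (adjusted p = 7.39e-05, adjusted p = 0.0197 with an estimated correlation). Of 21 superoxide and peroxide genes 6 rose and 1 fell, the same adjusted over the list alone, with sod-3 at 5.31 (SE 0.31, adjusted p = 3.99e-09) and prdx-3 at 0.78 (adjusted p = 0.00169, adjusted p = 0.0197 with an estimated correlation).

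Further rises were those of C07G1.7 at 8.50, ZK177.9 at 7.31, clec-17 at 5.60, the insulin-like ins-35 at 5.27, osg-1 at 5.21, cyp-33C8 at 5.11, adh-1 at 5.04, acs-2 at 4.85 and cyp-14A4 at 4.71. Falls included those of ilys-2 by 8.71, F49E12.10 by 7.28, lys-10 by 6.55, fat-7 by 6.11, ilys-3 by 5.85, nhr-114 by 4.10, wrt-4 by 4.03, lys-5 by 3.93 and clec-52 by 3.74. Over the 40 lysozymes, saposins and antimicrobial peptides 7 rose and 9 fell, 9 and 9 adjusted over the list alone, with no shift of the list against other genes past the test (adjusted p = 0.573). The phosphoenolpyruvate carboxykinase pck-1 rose by 2.13, and of 16 glycolytic genes 7 rose, 9 adjusted over the list alone, with aldo-1 at 2.36 and ldh-1 at 1.81 (adjusted p = 1.95e-06, adjusted p = 0.0617 with an estimated correlation). limma called 2192 probe sets, 1122 higher and 1070 lower, with 841 changed at least 2-fold. Without ced-4 replicates 1, 2 and 3 the count was 1456, 1417 and 1408, and without nuo-6 ced-4 replicates 1 and 2 it was 1427 and 1450. A fit of only these groups called 5426.

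Interaction terms tested whether each mitochondrial mutation acted differently with and without ced-4. For isp-1 the molting cycle genes ran lower than the sum of both mutations, 15 of 19 lower and 1 higher, 17 and 1 adjusted over the list alone, with wrt-4 at -7.05 and ptr-4 at -3.23 (adjusted p = 3.84e-15, adjusted p = 0.0165 with an estimated correlation). Of 62 neuropeptide genes 31 were lower and 1 higher, 35 and 1 adjusted over the list alone, with nlp-1 at -2.29 and nlp-55 at -1.84 (adjusted p = 1.04e-11, adjusted p = 0.306 with an estimated correlation). Of 56 sperm genes 35 were lower, 51 adjusted over the list alone (adjusted p = 1.43e-13, adjusted p = 0.632 with an estimated correlation). For isp-1 limma called 2362 probe sets, 1136 higher and 1226 lower. The count was 1534 and 1519 without ced-4 replicates 2 and 3, 1371 and 1503 without isp-1 ced-4 replicates 2 and 3, and 1307 in a fit of only the groups involved. The sperm and molting covariates left 0 by limma (1022 at an unadjusted p under 0.05), at a median SE of 0.987 in place of 0.29.

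For nuo-6 the lysozymes ran lower than the sum of both mutations, with 11 of 40 lysozymes, saposins and antimicrobial peptides lower, and 11 lower and 1 higher adjusted over the list alone (adjusted p = 0.00924, adjusted p = 0.857 with an estimated correlation). lys-10 had an interaction of -6.31 (SE 0.29, adjusted p = 4.14e-10) and ilys-2 of -8.40 (SE 1.22, adjusted p = 0.000781), whereas cth-1 had 5.69 (SE 1.12, adjusted p = 0.0054) and argk-1, an arginine kinase, 4.75 (SE 0.77, adjusted p = 0.00188). For nuo-6 limma called 1372 probe sets, 742 higher and 630 lower, and after loess 844 and 456. The count was 866 without nuo-6 replicate 3, 824, 832 and 798 without ced-4 replicates 1, 2 and 3, and 855, 841 and 820 without nuo-6 ced-4 replicates 1, 2 and 3. Across the mutations with no arrays in common, changes of isp-1 in wild type and in ced-4 correlated at 0.559 over probe sets against 0.011 simulated, and those of nuo-6 at 0.384 against -0.010. In these pairs 1018 and 718 probe sets were higher in both, where independent lists would share 486.7 and 202.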

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

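The tests on the molting pattern and on isp-1 replicate 1 were chosen only after the results they bear on had been seen, as was the separate scoring of the higher and lower parts of the common set. The splits of the wild type arrays were chosen after the data were seen, with their bound written before their values. For the sperm relation of the lower part of the common set, the bounds were written before the correlation was computed, but after the sperm list means of each array had been seen.

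In wild type, replicate 3 lay far from the other 3 arrays in the mean of the ATP synthase list, with a gap of 0.844 of the range, and in that of the C-type lectin list, with a gap of 0.873. These were 2 of 45 values tested, and chance alone gives about 1 in 20.

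The effect of isp-1 differed between worms with intact ced-4 and ced-4 mutants, by the interaction term, in several genes. It was more positive with the ced-4 mutation for clec-174 (4.18), clec-190 (4.14), clec-223 (4.07), clec-67 (3.81) and the chitinase cht-1 (3.80). For the cuticle genes col-97 (-7.75), col-104 (-7.77), col-49 (-7.84), col-48 (-8.26) and dpy-5 (-8.73) it was more negative, as for the molting cycle list, whose median interaction was -1.99. The molting list mean was 2.60 in ced-4, -0.05 in isp-1 and 0.03 in isp-1 ced-4. There the term shows mainly that the rise in ced-4 was absent in isp-1 ced-4. The same holds for col-48 and col-97, which rose in ced-4 and were lower by a similar size in isp-1 ced-4 against ced-4.

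The effect of nuo-6 was more positive in the ced-4 mutant for cth-1 (5.69), argk-1 (4.75), aakg-2 (4.45), the nuclear receptor nhr-17 (4.34) and vap-2 (4.25). It was more negative for the lysozyme genes ilys-3 (-4.64), lys-10 (-6.31) and ilys-2 (-8.40), and for catp-3 (-4.89) and clec-52 (-6.64). lys-10 and ilys-2 were near background in wild type and, at 1.89 and 2.77, in nuo-6 ced-4. For them the term shows mainly that the rise in ced-4 was absent in nuo-6 ced-4. For ilys-3 the call ended without nuo-6 ced-4 replicate 2, where the interaction was -4.56.

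The common set leaned to lower probe sets, and 4 of 56 sperm genes were among its lower part (adjusted p = 1 by Fisher's exact test). One possible cause was spread between the wild type arrays shared by the comparisons. Were it the whole cause, setting isp-1 and paraquat against different wild type arrays would have brought the number lower in both close to that of independent lists. The lowest ratio over the splits was 2.41, and 2.09 for nuo-6 and paraquat, which argues against such spread for the lower part. A difference of all wild type arrays from the other groups would remain in every split, so the splits cannot test it. The lower part was also shifted in ced-4 (0.643) and nuo-6 ced-4 (0.508), with an SD of 0.465 in wild type. For the higher part the lowest ratio was 3.45 for isp-1 and nuo-6, but 1.07 for isp-1 and paraquat and 0.983 for nuo-6 and paraquat. Shared wild type arrays thus stay open for the higher part. A candidate explanation is that some arrays held less sperm RNA: across 22 arrays, taken as deviations from their group means, the mean of the sperm list and the score of 734 lower probe sets outside that list had a Pearson r of -0.759 (permutation p = 0.00023, adjusted 0.00046) and a Spearman rho of -0.931 (permutation p = 0.00058, adjusted 0.00058), and r was -0.77 without isp-1 ced-4 replicates 1 and 3, the farthest arrays. With the means of the sperm and molting lists as covariates, the common set held 406 probe sets in place of 1307, 389 of them shared, and in paraquat the median SE went from 0.198 to 0.326 while the median size of the called changes went from 0.835 to 0.666. Both lists entered together, and the sperm list itself fell with paraquat, so this drop cannot be assigned to sperm RNA. The relation within groups does not show why arrays differ in sperm RNA or that it accounts for the differences between groups. In isp-1 the sperm list mean was -0.522 and the lower part shifted by 1.33. The lower part was chosen by its fall in isp-1, nuo-6 and paraquat, so these sizes cannot decide it. Effects of the mutations and of paraquat on sperm or on developmental timing stay open and untested.

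Molting cycle genes were high in ced-4 and nuo-6 ced-4 and not in isp-1 ced-4. Arrays of isp-1 ced-4 without the ced-4 mutation are argued against, since the highest ced-4 transcript value there differed from the lowest with intact ced-4 by -1.48. If ced-4 had been sampled earlier in development, vitellogenins and oocyte genes were to be lower by 0.5 or more. They differed from wild type by -0.296 and -0.019 (SD in wild type 0.191 and 0.224), so neither passed the bound. The vitellogenins clear it by little more than 1 SD, and the reading of this bound was revised after the values were seen. No array here comes from worms labelled as younger, so how far these lists fall with earlier sampling is not known. The values for ced-4 therefore do not settle it. For nuo-6 ced-4 earlier sampling may contribute, since vitellogenins differed by -0.689, past the bound, and oocyte genes by -0.259, short of it, so the values do not settle it. A biological effect of ced-4 that isp-1 changes stays open as well, and was not tested.

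isp-1 replicate 1 lay close to the nuo-6 arrays. On 457 probe sets that separated isp-1 replicates 2 and 3 from nuo-6 replicates 2 and 3, it lay 0.89 of the way to nuo-6, a position consistent with nuo-6 RNA in that sample. A swap with a nuo-6 array is argued against, since each nuo-6 array, left out of the choice of probe sets, lay at least 0.74 of the way. The isp-1 and nuo-6 transcripts cannot decide, and spread between isp-1 samples, or some difference of replicates 2 and 3 from the rest, stays open and untested.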

How the results depend on the processing

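The covariates and the higher and lower parts of the common set were chosen after seeing the data. The stricter filter, which tests 6699 probe sets, left 1210 calls in isp-1, 2039 in nuo-6, 2911 in paraquat, 429 in the common set, 8 in nuo-6 against isp-1, 825 in ced-4, 2448 in isp-1 ced-4 against isp-1, 1981 in nuo-6 ced-4 against nuo-6, 3475 in isp-1 ced-4 against ced-4, and 1439 and 301 in the isp-1 and nuo-6 interactions. With no filter nuo-6 against isp-1 had 2. Fitting only the groups compared takes the spread from fewer arrays and from those groups alone. It gave 716 in isp-1, 2190 in nuo-6, 853 in ced-4, 2088 in isp-1 ced-4 against isp-1 and 1307 in the isp-1 interaction. In nuo-6 against isp-1 limma called 0 (894 at an unadjusted p under 0.05), while nuo-6 ced-4 against ced-4 rose to 5426. The median SD was 0.298 in wild type but 0.124 in ced-4 and 0.126 in nuo-6 ced-4. The shared estimate of the main fit can thus understate the spread in comparisons with wild type and overstate it between ced-4 and nuo-6 ced-4.

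With the replicate number as a block there were 1295 calls in ced-4, 897 in the nuo-6 interaction and by limma 0 in nuo-6 against isp-1 (1395 at an unadjusted p under 0.05), and the calls of clc-10 in isp-1 (-2.002), nuo-6 in nuo-6 (0.29) and the ilys-3 interaction (-4.34) ended. Of 63 same-numbered pairs 12 correlated over 0.1 and 6 under -0.1, from -0.246 to 0.277, so the numbers do not pair the samples. With the means of the sperm and molting lists as covariates there were 1188 calls in paraquat, 406 in the common set, 4 in ced-4, 158 in isp-1 ced-4 against isp-1, and by limma 0 in nuo-6 ced-4 against nuo-6, isp-1 ced-4 against ced-4 and the isp-1 interaction (966, 973 and 1022 at an unadjusted p under 0.05). In ced-4 the median SE went from 0.198 to 0.933 and the median size of the called changes from 1.01 to 0.791, so calls ended mainly through the wider error there. The same holds for nuo-6 ced-4 against nuo-6 (SE 0.212 to 0.92, size 0.912 to 0.795), isp-1 ced-4 against ced-4 (0.212 to 1.01 and 0.957 to 0.869) and the isp-1 interaction (0.29 to 0.987 and 1.32 to 1.05). In isp-1 ced-4 against isp-1 they went from 0.212 to 0.319 and from 0.901 to 0.492, and in paraquat from 0.198 to 0.326 and from 0.835 to 0.666, so the changes shrank as well.

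Leaving out each array gave 2025 to 2928 calls in isp-1, 3309 to 4323 in nuo-6, 4383 to 5509 in paraquat, 937 to 1475 in the common set, 0 to 753 in nuo-6 against isp-1 (753 without isp-1 replicate 1), 1163 to 3404 in ced-4 (3404 without wild type replicate 1), 2748 to 4289 in isp-1 ced-4 against isp-1, 2780 to 3528 in nuo-6 ced-4 against nuo-6, 5324 to 6471 in isp-1 ced-4 against ced-4, 1408 to 1496 in nuo-6 ced-4 against ced-4, and 1371 to 2956 and 798 to 1959 in the isp-1 and nuo-6 interactions. For the score of the common set, isp-1 ced-4 lay above ced-4 by 0.794 in the higher part and 1.738 in the lower, and above isp-1 by 0.0201 and 1.052. nuo-6 ced-4 differed from nuo-6 by -0.569 and -0.891, and from ced-4 by 0.277 in the higher part, -0.135 in the lower, -0.0167 with medians, 0.015 after loess and 0.0056 with the set chosen without nuo-6.

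Of 142 called gene lists, 9 kept their call with an estimated correlation and 124 after loess, and 23 lost it with fry. After loess cytosolic ribosomal proteins in paraquat turned from lower (adjusted p = 0.0484, and adjusted p = 0.582 with an estimated correlation) to higher (adjusted p = 0.131). Of 1377 values of named genes, 1290 kept their side of the threshold after loess, 1276 with the block and 1370 with trend and robust options. Leaving out the array that mattered most, run for called genes only, ended 298 calls. Where no cause is given, the cause was not tested. Genes near the median of the table carry little signal over background, which limits them.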

Other observations

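The relations given here use the planned comparisons and their splits. In nuo-6, 9 of 23 DAF-16 associated genes rose, 11 adjusted over the list alone, with cdr-2 at 2.77 (adjusted p = 0.000383, and adjusted p = 0.283 with an estimated correlation). In isp-1 ced-4 against isp-1, 9 of 14 insulin-like peptide genes fell, 10 lower and 1 higher adjusted over the list alone, with ins-30 by 1.97 (adjusted p = 0.00458, and adjusted p = 0.446 with an estimated correlation). With paraquat, 7 of 14 genes of the intrinsic apoptosis pathway rose, 7 adjusted over the list alone, with ced-8 at 1.62 and cep-1, the p53 homologue, at 0.62, while the list as a whole did not pass (adjusted p = 0.194). On the same arrays the oocyte list mean was 0.796, the germline list mean 0.311 and the sperm list mean -1.989. C-type lectins went both ways in isp-1 ced-4 against ced-4, 15 of 63 higher and 14 lower, 15 and 13 adjusted over the list alone, with a median of -0.09, a mean of 0.138 and no call (adjusted p = 0.874, in the lower direction).

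Other splits of the same arrays into groups of the same sizes were counted. Of 35 splits, 1 (the real one) gave as many calls for isp-1 (2775, highest other 1769), for nuo-6 (4150, highest other 2602) and for paraquat (5251, highest other 4163). These shares lie under 0.05 and argue against chance assignment of arrays there. For the common set 1 of 100 splits gave as many (1307 calls, highest other 655). Its splits shuffle arrays over wild type, isp-1, nuo-6 and paraquat together. They show that these groups differ and do not exclude chance for the sharing of changes by itself. For the nuo-6 interaction 1 of 100 splits gave as many (1372 calls, highest other 842). The splits for interactions shuffle arrays over all the groups involved and so break up the main effects too. They therefore do not exclude chance for an interaction by itself. For ced-4, 2 of 35 splits gave as many calls (1999, highest other 3523), so this count does not exclude chance. The split with 3523 set all 3 ced-4 arrays and wild type replicate 1 against the other wild type arrays, so it still holds the ced-4 difference and points to a structure of the samples. For the isp-1 interaction 5 of 100 splits gave as many (2362, highest other 5501), so chance is not excluded there either. The split with 5501 contrasts all wild type and ced-4 arrays with all isp-1 and isp-1 ced-4 arrays, which points to that structure of the samples.

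With 3 against 3 arrays the 10 splits are too few for a share under 0.05. In nuo-6 against isp-1, 3 of 10 splits gave as many calls (1, highest other 482). In the comparisons of the double mutants 1 of 10 did, with 4193 calls in isp-1 ced-4 against isp-1 (highest other 403), 3778 in nuo-6 ced-4 against nuo-6 (highest other 0 by limma), 6594 in isp-1 ced-4 against ced-4 (highest other 1) and 2192 in nuo-6 ced-4 against ced-4 (highest other 0 by limma).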
